A study of Caenorhabditis elegans with 52 samples.

How the data were processed

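Small RNAs of whole adult Caenorhabditis elegans were sequenced in 42 libraries that fall into 21 groups of 2 replicates. Per the labels' protocols, the small RNAs were treated with the RNA phosphatase PIR-1 before library construction, and animals were collected as day 1 adults. The deposited table gives piRNA levels in RPM, which the authors scaled to the sequencing depth of each library per the labels. The submitters' processing notes name Trim Galore and Bowtie without versions. The genome build was not given in the sources used here, so piRNAs are named by symbol and placed only by chromosome and neighbourhood. A further 10 samples of the series, 4 of mRNA and 6 of other poly(U) polymerase mutants, were not analysed here.

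The table held 14681 entries, of which 1 piRNA was listed more than once, leaving 14680 piRNAs. All 14680 identifiers matched a gene name, and 14669 carried the same name as in the table. The time-course part listed 14052 piRNAs and the steady-state part 14581. The values were multiples of a twelfth of 1 read, which gave each library's depth, between 8807176 and 52798564 reads. Between 85.8% and 88.2% of values per library came to a whole read within 0.01 read, so the rest held reads divided between loci. A level of 0 allows up to 3 reads, between 0.0568 and 0.341 RPM over the libraries, and such floors cover counting error only. piRNAs with divided reads in any library made up between 25.1% and 27.4% of those tested, and the named ones are marked as sharing reads.

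Each comparison was fitted with limma 3.58.1 in R 4.3.3 on log2(RPM + 0.5), with a trended prior variance, for piRNAs with a mean of at least 1 RPM over the libraries of the fit. Changes are on that scale, which understates the change of low piRNAs. Values were not rescaled between libraries, since rescaling over piRNAs would remove a change shared by most of them. A piRNA rose or fell where the Benjamini-Hochberg adjusted p was under 0.05. All adjusted p-values below come from limma unless another test is named. The control and both disl-2 alleles shared 1 fit, as did the 4 groups of the pup-1 experiment and the 20 libraries of the time course. In the time course, log2 level was regressed on hours of auxin in each genotype, and a half-life is the negative inverse of that slope. Total piRNA level is the sum over the table, compared by a two-sided exact permutation test. With 2 libraries against 2 that test cannot give a p below 0.333. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. In the steady-state fits that spread is largely pooled over piRNAs. The prior had 1825 degrees of freedom against 2 residual ones in parn-1; disl-2, and 62.6 against 3 in the disl-2 fit. Very small adjusted p-values rest on this pooling.

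The piRNAs named in the text follow 1 rule. Among piRNAs past the threshold with a mean of at least 5 RPM in the compared groups and libraries that do not overlap, the 10 largest rises and the 10 largest falls qualify, or the steepest and shallowest slopes for decay. The 5 most abundant piRNAs of the control group and 21ur-1 qualify whatever their values. The text names a part of these. The comparisons, tests, naming rule, lists and most alternatives were fixed before the data were examined.

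Lists were tested with camera in limma, with a preset correlation of 0.01 between piRNAs and again with an estimated correlation. They were the 2 piRNA clusters of chromosome IV (cluster a nearer the left end and cluster b nearer the right end), the rest of chromosome IV, the other chromosomes, piRNAs inside or outside an annotated coding gene, and abundance quartiles ranked in control libraries outside the comparison. Gene neighbourhoods came from the WBcel235 gene table. The authors' classes, Spermatogenic, Oogenic and none, were added as lists after the data were seen. Lists by sequence, such as the base at the 3′ end, need a genome and were not analysed here. The preset camera calls given below were lost with an estimated correlation, except that of the other chromosomes in the disl-2(how27) time course.

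Alternatives were a pseudocount of 0.1 or 2, no filter, a mean of at least 5 RPM, rescaling to equal medians, 1 fit over all libraries, replicate number as a block, and leaving out each library in turn. Limma voom on estimated reads and a fit of disl-2(how27) without the disl-2(tm5337) libraries were chosen after seeing the data. A planned count-based test was not run, because the values were not whole reads. Comparisons that share controls were set against 100 simulated sets of unchanged groups.

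The fits were tested on simulated data with 200 of the tested piRNAs changed, 100 by 1 and 100 by 2 on the log2 scale. For disl-2(how27), with 5618 piRNAs, 53% of changes of 1 and 100% of changes of 2 were recovered, and 7 unchanged piRNAs were called. The shares were 55% and 99% for disl-2(tm5337), 28% and 95% for henn-1; disl-2 with 8769 piRNAs, and 51% and 98% for parn-1; disl-2 with 4039 piRNAs. In the pup-1 experiment, with 5120 piRNAs, they were 60% and 98% for pup-1, 57% and 99% for pup-1; disl-2(how27), and 51% and 99% for pup-1; disl-2(tm5337). At 0 h of the time course, with 4112 piRNAs, they were 37% and 99%. For the difference in decay, 29% of differences of 0.1 per hour and 80% of 0.2 per hour were recovered. The simulated noise was independent between piRNAs. In the data camera estimated correlations such as 0.40, in the third abundance quartile of disl-2(how27). Shares recovered and false calls therefore do not cover noise that a whole library shares. Replicates differed by more than sampling noise in every group, with a chi-square per degree of freedom between 2.14 and 38.6. The highest was that of henn-1, followed by 17.0 in pup-1; disl-2(how27). Figures were drawn with matplotlib 3.10.9, and tables were read with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.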

Results

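piRNA levels were measured by small RNA sequencing of adult Caenorhabditis elegans lacking DISL-2, a homolog of the 3′ to 5′ exonuclease DIS3L2. piRNAs are germline small RNAs of the Piwi protein PRG-1, and in this species most are transcribed from 2 clusters on chromosome IV. In the steady-state part, 22 libraries compared disl-2 mutants with an isogenic control, and disl-2 double mutants with henn-1, parn-1 or pup-1 mutants. HENN-1 methylates piRNA 3′ ends, PARN-1 trims them and PUP-1 is a poly(U) polymerase. In the time-course part, 20 libraries followed piRNAs for up to 12 h after 4 mM auxin was given to deplete TOFU-5, a factor for piRNA transcription. Each group had 2 libraries, at depths between 8807176 and 52798564 reads. The mRNAs of disl-2, henn-1, parn-1 and pup-1 are not part of the piRNA table, so the mutations were not checked in the libraries.

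**Figure D1:**
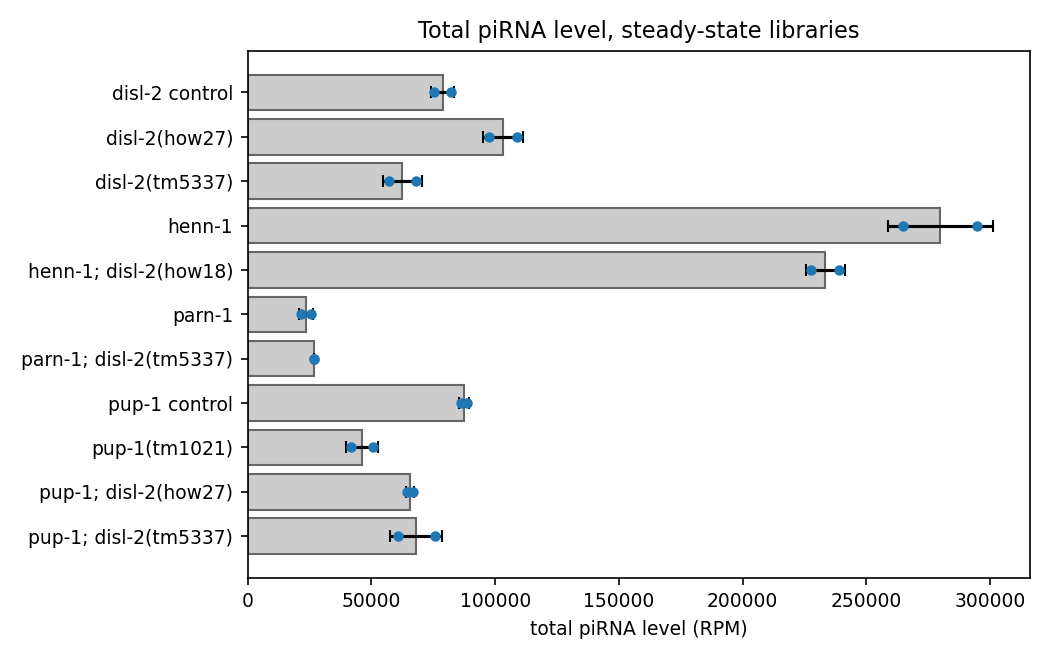
Total piRNA level in RPM for the 11 steady-state groups. Bars give the mean, error bars the SD and points the 2 libraries of each group, with the henn-1 mean at 279745 RPM and the parn-1 mean at 23609 RPM.

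The first question was whether piRNA levels differ without DISL-2. Total piRNA level was 103017 ± 8068 RPM (SD, n = 2) in disl-2(how27) and 78740 ± 4780 RPM in the control, a 1.31-fold ratio (log2 0.39 ± 0.10 SE). The libraries did not overlap, and the two-sided exact permutation p was 0.333, the smallest that 2 against 2 allows. Of 5618 piRNAs tested, 1160 rose and 2 fell, with a median log2 change of 0.47. The piRNA 21ur-7472 rose from 3.06 ± 1.25 to 13.3 ± 1.91 RPM (log2 1.99 ± 0.29, adjusted p = 1.8e-05). Rises were also called for 21ur-7828, from 9.0 to 30.5 RPM, 21ur-5849, from 16.7 to 46.4 RPM, 21ur-7067, from 4.35 to 14.0 RPM, and the Oogenic piRNAs 21ur-7135 (log2 1.51) and 21ur-5766 (log2 1.53). The rise of 21ur-13756 (log2 1.97) is uncertain because it shares reads. The piRNAs that fell were 21ur-425, from 15.2 to 7.90 RPM (log2 -0.91 ± 0.28, adjusted p = 0.0172), and 21ur-6193 (log2 -0.80, adjusted p = 0.0447). Among abundant piRNAs, 21ur-2446 rose from 752 to 1051 RPM (log2 0.48, adjusted p = 0.0336), while 21ur-3730 was at 757 and 943 RPM (adjusted p = 0.133) and 21ur-3545 at 477 and 483 RPM (adjusted p = 0.962). The piRNA 21ur-1 was at 8.66 and 10.5 RPM (adjusted p = 0.484). After rescaling to equal medians, which moved the median by 0.51, 76 piRNAs rose, 98 fell, and 21ur-2446 lay at -0.10. The number that rose was 1 without disl-2(how27) replicate 1, 414 without disl-2(how27) replicate 2, and 462 and 169 without control replicates 1 and 2. With no filter on low values limma called 0 piRNAs, with 3345 at an unadjusted p under 0.05, while limma voom with the filter called 866 rises.

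By position, cluster a of chromosome IV gained more than cluster b in disl-2(how27). In cluster a, 384 of 881 piRNAs rose and 0 fell by limma, with a median log2 change of 0.72, and 522 rose when adjusted over the list alone. In cluster b, 747 of 4653 rose and 2 fell, with a median of 0.43, and 628 rose when adjusted over the list alone. The camera test set cluster a above the other piRNAs (adjusted p = 5.8e-14), a call not held at adjusted p = 0.898 with an estimated correlation. After rescaling, the median was 0.20 in cluster a and -0.08 in cluster b. Of piRNAs on the rest of chromosome IV, 29 of 81 rose, and of 3 on other chromosomes 0 were called by limma. Inside coding genes 472 of 2007 rose, and outside them 688 of 3611 rose (camera adjusted p = 0.154 for both). From the least to the most abundant quartile, 305, 304, 309 and 242 piRNAs rose, and the most abundant quartile was set below the rest (camera adjusted p = 0.0151, and adjusted p = 0.945 with an estimated correlation). In the authors' classes, added after the data were seen, 542 of 1904 Spermatogenic piRNAs rose (median log2 0.58) against 131 of 1045 Oogenic piRNAs (median log2 0.32). The camera adjusted p was 1.1e-05 for Spermatogenic and 2.2e-05 for Oogenic, and adjusted p = 0.945 with an estimated correlation for both. After rescaling, the Oogenic median lay at -0.20.

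The second allele, disl-2(tm5337), gave another profile against the same control. Total piRNA level was 62505 ± 7816 RPM, 0.791 of the control (log2 -0.34 ± 0.14, exact permutation p = 0.333, n = 2). That difference ran from -0.47 to -0.21 with 1 library left out, and was -0.19 for the median piRNA in place of the total. Of 5618 piRNAs, 760 rose and 1511 fell, with a median log2 change of -0.19. The Oogenic piRNA 21ur-8985 fell from 24.3 ± 3.22 to 1.41 ± 0.07 RPM (log2 -3.69 ± 0.27, adjusted p = 5.3e-18), and 21ur-4151 from 38.6 to 2.80 RPM (log2 -3.64). Falls were also called for 21ur-1120 (log2 -3.49), 21ur-1504, from 30.4 to 2.80 RPM, 21ur-326, from 19.0 to 1.61 RPM, and the abundant 21ur-3545, from 477 to 145 RPM (log2 -1.71, adjusted p = 1.6e-11). The abundant 21ur-2446 fell from 752 to 458 RPM. In the other direction, 21ur-4894 rose from 2.41 to 17.8 RPM (log2 2.63 ± 0.30, adjusted p = 8.0e-11), 21ur-2400 from 2.16 to 14.4 RPM, 21ur-2194 from 4.51 to 24.9 RPM, 21ur-4985 from 8.69 to 41.9 RPM, and 21ur-9190 by a log2 change of 2.63. 21ur-3730 was at 757 and 737 RPM (adjusted p = 0.908) and 21ur-1 at 8.66 and 8.01 RPM (adjusted p = 0.825). In the most abundant quartile 149 piRNAs rose and 607 fell of 1405 (camera adjusted p = 5.7e-06, and adjusted p = 0.982 with an estimated correlation); adjusted over the list alone, 163 rose and 632 fell. The medians of cluster a and cluster b were -0.20 and -0.18. Spermatogenic piRNAs had 146 rises and 583 falls of 1904 (median log2 -0.32, and -0.20 after rescaling). Oogenic piRNAs had 205 rises and 256 falls of 1045, with a median of -0.13 that rescaling turned to 0.00888. The camera adjusted p was 0.0529 for Spermatogenic and 0.322 for Oogenic, and adjusted p = 0.982 for both with an estimated correlation. Rescaling moved the median by -0.12 and gave 1248 rises and 1546 falls. The number that rose was 427 without disl-2(tm5337) replicate 1, and 499 and 487 without control replicates 1 and 2; falls numbered 1010 without control replicate 1.

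Set against each other, the alleles shared 251 of their rises, where independent lists would share 157. Another 256 of the 1160 piRNAs that rose in disl-2(how27) fell in disl-2(tm5337), against 1511 falls among all 5618 tested. These opposite calls were fewer than independent lists would give. After rescaling, 41 rises were shared against 16.9 for independent lists. Of the 76 rises in disl-2(how27), 6 had those opposite calls, against 1546 falls in disl-2(tm5337) among all 5618 piRNAs. Without disl-2(how27) replicate 1, which left 1 rise in disl-2(how27), there were 0 of each. Without disl-2(tm5337) replicate 1 there were 210 shared rises and 564 opposite calls, and without its replicate 2, 461 and 300. Across 5618 piRNAs, which are not independent replicates, the Spearman correlation of the changes was 0.21, with 0.48 in simulated unchanged groups that share controls. The covariance was 0.0635 and the simulated covariance 0.0418. Part of the excess may come from the shared controls, which are too few to divide. With the alleles pooled in 1 contrast, 664 piRNAs rose and 245 fell, and the total was 1.02 of the control (exact permutation p = 0.933, smallest possible 0.0667). Its log2 of 0.02 ran from -0.12 to 0.19 with 1 library left out, and was 0.22 for the median piRNA in place of the total. 21ur-4375 rose from 3.33 to 14.3 RPM (log2 1.86 ± 0.26, adjusted p = 7.3e-07), and 21ur-4894 by a log2 change of 1.71. 21ur-13756, which shares reads, had a change of 1.48. 21ur-1069 fell (log2 -1.58), as did 21ur-4238 (log2 -1.44), 21ur-425 (log2 -1.46) and 21ur-3545 (log2 -0.85). After rescaling, by which the median moved 0.20, 688 rose and 922 fell. The numbers were 327 rises and 93 falls without control replicate 1, 214 and 118 without control replicate 2, and 283 and 135 without disl-2(how27) replicate 1. Falls numbered 120 without disl-2(how27) replicate 2 and 394 without disl-2(tm5337) replicate 1, and rises 1184 without disl-2(tm5337) replicate 2.

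Loss of DISL-2 was next examined where HENN-1 is missing. The henn-1 libraries held 279745 ± 21178 RPM of piRNAs and the henn-1; disl-2(how18) libraries 233391 ± 7963 RPM (log2 -0.26 ± 0.08, exact permutation p = 0.333, n = 2). The median piRNA in place of the total turned that difference to log2 0.25. The henn-1 replicates differed more than those of any other group, with a chi-square per degree of freedom of 38.6, against 4.54 in henn-1; disl-2. Of 8769 piRNAs, 1553 rose and 876 fell, with a median log2 change of 0.12 that lay at -0.10 after rescaling. 21ur-5230 rose from 6.98 ± 5.05 to 121 ± 41.3 RPM (log2 4.17 ± 0.49, adjusted p = 0.0120), 21ur-8612 from 0.876 to 22.0 RPM, 21ur-5108 from 2.93 to 47.5 RPM, and the Oogenic 21ur-623 from 43.1 to 275 RPM. 21ur-2400 fell from 52.1 to 5.20 RPM (log2 -3.22 ± 0.29, adjusted p = 0.0120), 21ur-3376 from 31.0 to 3.78 RPM, 21ur-4910 from 114 to 16.7 RPM, and the abundant 21ur-2200 from 1459 ± 789 to 442 ± 44.3 RPM (adjusted p = 0.0265). 21ur-3545 was at 1651 and 1157 RPM (adjusted p = 0.163) and 21ur-1 at 108 and 118 RPM (adjusted p = 0.670). In cluster a, 627 of 1377 piRNAs rose and 8 fell, with a median log2 change of 0.84, and 737 rose when adjusted over the list alone. In cluster b, 896 of 7252 rose and 858 fell, with a median of -0.01. Camera set cluster a above the rest (adjusted p = 1.0e-21, and adjusted p = 0.124 with an estimated correlation), and its median was 0.63 after rescaling. Spermatogenic piRNAs had 538 rises and 66 falls of 2540, and Oogenic piRNAs 117 rises and 263 falls of 1471 (camera adjusted p = 0.00231 and 1.3e-05, and adjusted p = 0.0985 and adjusted p = 0.413 with an estimated correlation). Rescaling moved the median by 0.22 and gave 1154 rises and 1387 falls. The numbers were 3423 rises and 2345 falls without henn-1 replicate 1, 2500 and 1758 without henn-1 replicate 2, 521 and 186 without henn-1; disl-2 replicate 1, and 448 and 118 without henn-1; disl-2 replicate 2.

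Where PARN-1 is missing, piRNA totals were lower than in the other steady-state groups, at 23609 ± 2935 RPM in parn-1 and 26946 ± 59.2 RPM in parn-1; disl-2(tm5337) (log2 0.20 ± 0.13, exact permutation p = 0.333, n = 2, and log2 0.07 to 0.32 with 1 library left out). Of 4039 piRNAs, 989 rose and 405 fell. 21ur-5841 rose from 0.916 ± 0.173 to 10.3 ± 2.21 RPM (log2 2.92 ± 0.32, adjusted p = 1.9e-16), 21ur-2245 from 4.24 to 27.4 RPM, 21ur-8114 from 3.18 to 17.1 RPM, 21ur-7067 from 1.59 to 9.13 RPM, and 21ur-9601 by a log2 change of 2.60. 21ur-1780 fell from 9.11 to 0.945 RPM (log2 -2.70 ± 0.32, adjusted p = 3.9e-14), 21ur-8985 from 8.58 to 2.30 RPM, and 21ur-5568, which shares reads and is uncertain, from 28.1 to 5.24 RPM. Of the most abundant piRNAs, 21ur-5139 fell from 169 ± 21.2 to 66.1 ± 20.5 RPM and 21ur-5297 rose from 106 to 161 RPM. In cluster a, 315 of 511 piRNAs rose and 1 fell, with a median log2 change of 0.94, and 344 rose when adjusted over the list alone. In cluster b, 662 of 3492 rose and 403 fell, with a median of 0.12 that lay at -0.11 after rescaling. The camera adjusted p was 1.1e-24 for cluster a, and adjusted p = 0.567 with an estimated correlation. Spermatogenic piRNAs had 436 rises and 17 falls of 1065, and Oogenic piRNAs 83 rises and 151 falls of 878 (camera adjusted p = 1.9e-11 and 9.8e-08, and adjusted p = 0.862 and adjusted p = 0.896 with an estimated correlation). Rescaling moved the median by 0.23 and gave 716 rises and 756 falls, and no filter gave 0 of each by limma, with 3183 piRNAs at an unadjusted p under 0.05, against 938 and 399 by limma voom with the filter. The numbers were 539 and 165 without parn-1; disl-2 replicate 1, 523 and 51 without parn-1 replicate 1, and 398 and 212 without parn-1 replicate 2.

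**Figure D2:**
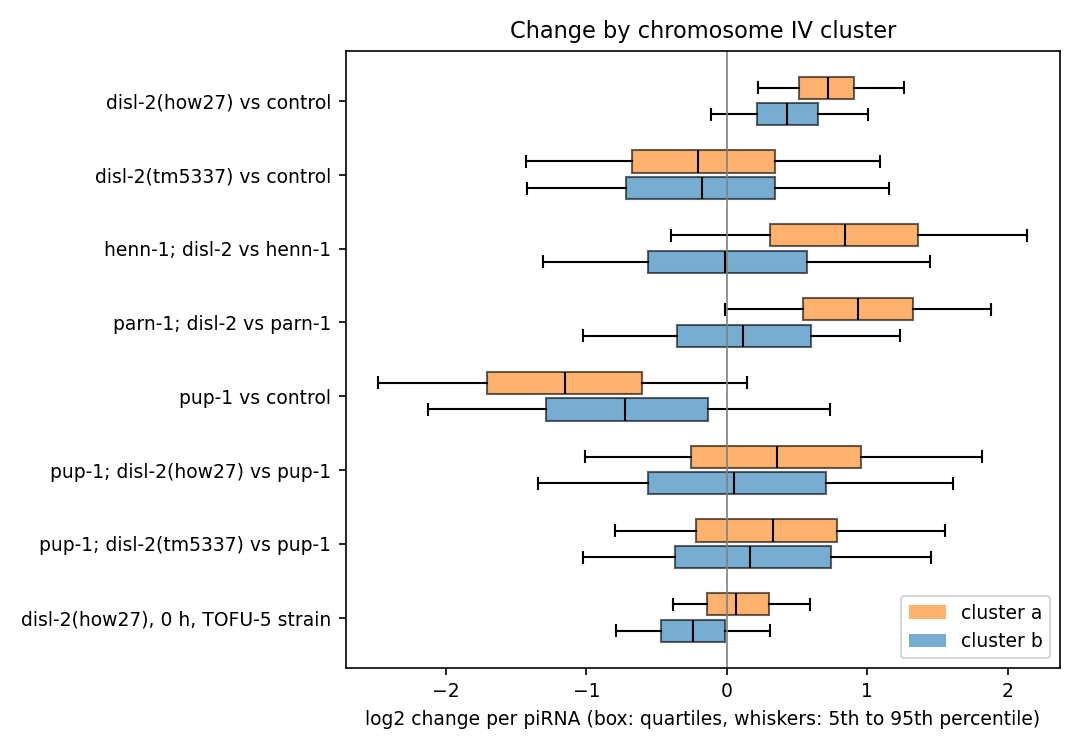
log2 change per piRNA in cluster a (orange) and cluster b (blue) of chromosome IV for 8 comparisons. Boxes give quartiles with the median as a line, and whiskers run from the 5th to the 95th percentile of piRNAs; the medians in parn-1; disl-2 were 0.94 and 0.12, and in disl-2(tm5337) -0.20 and -0.18.

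The pup-1 mutant was compared with its paired control. Total piRNA level was 46235 ± 6513 RPM in pup-1(tm1021) and 87362 ± 1877 RPM in the control, a ratio of 0.527 (log2 -0.93 ± 0.15, exact permutation p = 0.333, n = 2). Of 5120 piRNAs, 244 rose and 2727 fell, with a median log2 change of -0.78. 21ur-1504 fell from 103 ± 16.7 to 3.18 ± 0.14 RPM (log2 -4.81 ± 0.31, adjusted p = 8.5e-12), 21ur-326 from 34.0 to 1.58 RPM, 21ur-8114 from 110 to 11.8 RPM, the abundant 21ur-3545 from 568 to 120 RPM, and 21ur-1 from 24.8 to 5.25 RPM (log2 -2.14, adjusted p = 7.9e-07). The falls of 21ur-1956 (log2 -4.93) and 21ur-739 (log2 -1.61) are uncertain because these share reads. 21ur-3322 rose from 0.684 to 10.5 RPM (log2 3.22 ± 0.34, adjusted p = 2.9e-08), 21ur-2516 from 2.79 to 17.9 RPM and 21ur-4985 from 5.38 to 21 RPM, and 21ur-73, with shared reads, from 40.4 to 125 RPM. In cluster a, 8 of 725 piRNAs rose and 509 fell (519 adjusted over the list alone), with a median of -1.15, and in cluster b 233 of 4317 rose and 2185 fell, with a median of -0.72. The camera adjusted p was 1.1e-05 for cluster a, and adjusted p = 0.956 with an estimated correlation. Rescaling moved the median by -0.72 and gave 974 rises and 1087 falls, with the cluster b median at 0.00. Leaving out 1 library gave between 124 and 146 rises, fewest without control replicate 2, and 1778 falls without pup-1 replicate 2.

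Both disl-2 alleles were combined with pup-1 alleles that differ from each other and from the one in the single mutant. These comparisons therefore carry those differences too. Total piRNA level was 65570 ± 1786 RPM in pup-1; disl-2(how27), 1.43-fold that of pup-1 (log2 0.51 ± 0.15), and 68078 ± 10591 RPM in pup-1; disl-2(tm5337), 1.47-fold (log2 0.56 ± 0.21), each with an exact permutation p of 0.333 and n = 2. Of 5120 piRNAs, 1302 rose and 853 fell with disl-2(how27), and 1218 rose and 490 fell with disl-2(tm5337). The median log2 changes per piRNA were smaller than those of the totals, at 0.09 and 0.19, and the median piRNA in place of the total gave log2 differences of 0.12 and 0.18. 21ur-1078 rose from 18.1 ± 3.02 to 145 ± 10 RPM with disl-2(how27) (log2 2.97 ± 0.27, adjusted p = 1.6e-08), 21ur-742 from 27.9 to 221 RPM, and the abundant 21ur-3730 from 319 to 1119 RPM. With disl-2(tm5337), 21ur-3730 rose to 901 RPM (adjusted p = 8.1e-05). Rises of 21ur-1956 (log2 4.53 and 5.44), 21ur-6228 (log2 2.82 and 2.51), 21ur-4502 (log2 2.78) and 21ur-5876 (log2 2.64) are uncertain because these share reads, as is the fall of 21ur-739 from 293 to 133 and 186 RPM. 21ur-2516 fell from 17.9 to 2.58 and 4.17 RPM, and 21ur-4350 from 10.9 to 1.40 RPM with disl-2(how27), and 21ur-2005 from 9.46 to 1.24 RPM with disl-2(tm5337). 21ur-1 was at 5.25 RPM in pup-1 and at 4.67 and 5.42 RPM in the double mutants (adjusted p = 0.695 and 0.927). In the most abundant quartile, 551 of 1280 piRNAs rose with disl-2(how27) and 603 with disl-2(tm5337), against 169 and 119 in the least abundant (565, 652, 158 and 95 adjusted over the list alone). The camera adjusted p for the most abundant quartile was 1.1e-07 and 5.2e-14, and adjusted p = 0.795 and adjusted p = 0.834 with an estimated correlation. Spermatogenic piRNAs had 726 rises and 61 falls of 1677 with disl-2(how27), and 558 and 47 with disl-2(tm5337). Oogenic piRNAs had 111 rises and 303 falls of 1003 with disl-2(how27), and 147 and 161 with disl-2(tm5337). The camera adjusted p was 2.7e-15 and 4.6e-08 for these classes with disl-2(how27), and adjusted p = 0.723 for both with an estimated correlation. With disl-2(tm5337) it was 5.7e-06 and 0.00138, and adjusted p = 0.917 for both with an estimated correlation. The double mutants shared 1018 rises, where independent lists would share 310, and 448 falls against 81.6. Their changes had a Spearman correlation of 0.92 across piRNAs, against 0.48 in simulated unchanged groups, and a covariance of 0.649 against 0.0484 simulated. Part of the excess may come from the shared controls. The simulated groups also leave out the difference in pup-1 allele from the single mutant, which both double mutants carry. The excess therefore does not measure the disl-2 alleles alone. Rescaling moved the median of pup-1; disl-2(tm5337) by 0.11 and gave it 1187 rises and 767 falls. Without pup-1 replicate 1 falls numbered 369 with disl-2(how27) and 136 with disl-2(tm5337), and without pup-1 replicate 2 rises numbered 673 and 439. Falls with disl-2(how27) numbered 559 without pup-1 replicate 2, and those with disl-2(tm5337) 215 without pup-1 replicate 2 and 263 without double mutant replicate 2. Without pup-1; disl-2(tm5337) replicate 1, 432 rose.

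At 0 h of auxin in the TOFU-5 strain, disl-2(how27) was again compared with wild-type disl-2. The labels give 4 mM auxin for these libraries too. Total piRNA level was 38423 ± 6825 RPM in disl-2(how27) and 48624 ± 5315 RPM in wild type (log2 -0.35 ± 0.21, exact permutation p = 0.333, n = 2, and log2 -0.53 to -0.16 with 1 library left out). Of 4112 piRNAs, 4 rose and 64 fell. 21ur-425 fell from 9.56 ± 1.28 to 3.55 ± 0.46 RPM (log2 -1.31 ± 0.24, adjusted p = 0.00819), 21ur-537 from 24.0 to 10 RPM and 21ur-3149 from 92.1 to 40.8 RPM. The falls of 21ur-88 (log2 -1.18) and 21ur-3375 (log2 -0.81) are uncertain because these share reads. 21ur-7241 rose from 6.13 to 16.6 RPM (log2 1.36, adjusted p = 0.00683) and 21ur-6895 from 8.10 to 18.4 RPM. 21ur-3730 was at 456 and 257 RPM (adjusted p = 0.0772) and 21ur-1 at 10.7 and 8.41 RPM (adjusted p = 0.582). The cluster a median was 0.07 and the cluster b median -0.24 (camera adjusted p = 4.4e-16 for cluster a, and adjusted p = 0.306 with an estimated correlation), and 0.20 and -0.09 after rescaling. Rescaling moved the median by -0.15 and gave 3 rises and 2 falls. Without wild-type replicate 1 or 2 limma called 0 piRNAs, with 501 and 309 at an unadjusted p under 0.05 and 112 by voom on all libraries; without disl-2 replicates 1 and 2 there were 17 and 1 falls.

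Depletion of TOFU-5 was used to follow the loss of piRNAs over hours of auxin. The labels give auxin for every time-course library, so no untreated animals were followed over the same hours. Neither TOFU-5 nor piRNA transcription was measured in the libraries. Slopes, half-lives and decay therefore stand for the fall in RPM with time. Loss after transcription stops could not be separated from other changes over the 12 h. In wild-type disl-2, total piRNA level went from 48624 ± 5315 RPM at 0 h to 19219 ± 917 RPM at 12 h, with a half-life of 8.88 ± 1.15 h (SE). In disl-2(how27) it went from 38423 ± 6825 to 20597 ± 1456 RPM, with a half-life of 13.2 ± 2.05 h. The slopes of -0.113 ± 0.0146 and -0.0755 ± 0.0117 per hour differed by 0.0371 ± 0.0186 (two-sided exact permutation p = 0.0296, 7776 regroupings within time points, n = 2 per genotype and time). Without the 0 h time point the difference was 0.0258 (exact permutation p = 0.241), and the p ran from 0.0185 to 0.438 over all alternatives; without the 12 h time point the difference was 0.0839. Leaving out replicate 1 or 2 of both genotypes gave exact permutation p-values of 0.250 and 0.438, where the smallest possible is 0.0625.

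**Figure D3:**
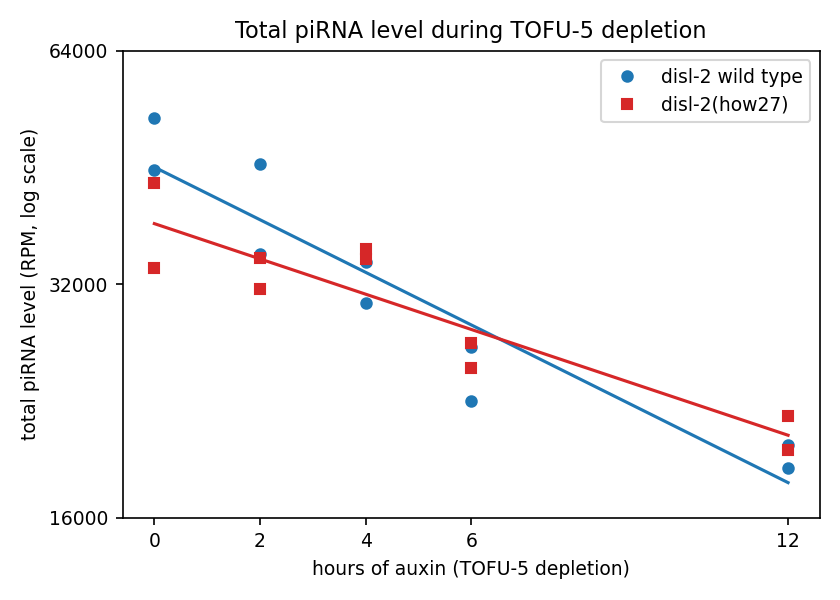
Total piRNA level in RPM, on a log axis, against hours of auxin. Points are libraries and lines are regressions per genotype, with half-lives of 8.88 h for disl-2 wild type (blue circles) and 13.2 h for disl-2(how27) (red squares).

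Among single piRNAs, 3369 of 4112 fell and 8 rose over the time course in wild-type disl-2, with a median slope of -0.10 per hour, and 2577 fell and 8 rose in disl-2(how27), with a median slope of -0.07. 21ur-2656 fell from 19.8 to 2.23 RPM with a half-life of 3.91 h (slope -0.26 ± 0.02, adjusted p = 5.2e-09), and 21ur-5677 had a half-life of 3.94 h and 21ur-3476 and 21ur-1281 of 3.99 h. 21ur-2545 had a half-life of 25.0 h (adjusted p = 0.0498) and 21ur-73, with shared reads, of 20.0 h; after rescaling both slopes were positive. 21ur-3730 had a half-life of 6.49 h in wild type and 11.1 h in disl-2(how27), and 21ur-1 of 9.17 and 14.4 h. 21ur-3375, with shared reads, was at 265 and 163 RPM at 0 and 12 h (adjusted p = 0.0860). 21ur-5493 rose from 12.3 to 23.6 RPM (adjusted p = 0.0465), and lay at a slope of -0.01 without the 12 h time point. The near-identical 21ur-2686 and 21ur-9424, uncertain for shared reads, rose from 60 and 60.3 to 126 RPM. In disl-2(how27) the steepest were 21ur-2807, 21ur-3698 and 21ur-887, with half-lives of 5.23, 5.49 and 5.79 h; 21ur-5059 had 23.5 h, and 21ur-2686 rose from 47.8 to 84.9 RPM. In wild type 1358 of 1473 Spermatogenic piRNAs fell (median slope -0.13) and 570 of 764 Oogenic piRNAs (median slope -0.09), with camera adjusted p = 5.4e-09 and 9.6e-04, and adjusted p = 0.785 and adjusted p = 0.859 with an estimated correlation. After rescaling the Oogenic median slope was 0.02. In disl-2(how27) the other chromosomes had 0 of 5 piRNAs called by limma, a median slope of 0.02 and a camera adjusted p of 1.3e-07, and adjusted p = 9.2e-04 with an estimated correlation. Camera also set this list above the rest in wild type, where its median slope of -0.03 turned to 0.08 after rescaling (camera adjusted p = 0.00120, and adjusted p = 0.0512 with an estimated correlation). Its difference between genotypes had a camera adjusted p of 0.736. Rescaling gave 469 rises and 550 falls in wild type and 99 and 61 in disl-2(how27). Without the 12 h time point disl-2(how27) had 51 rises and 1433 falls, and without its 12 h replicate 2 it had 0 rises. Without its 0 h replicate 1 or 2 it had 4 rises, and without its 2 h replicate 2 it had 5.

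The slope difference between genotypes was positive for 81.6% of 4112 piRNAs, with a median of 0.03 per hour. Limma called 0 piRNAs and limma voom 0, with 520 at an unadjusted p under 0.05, of which 514 were positive. After rescaling the median difference was 0.00364 per hour, 54.0% of piRNAs were positive, and 294 had an unadjusted p under 0.05, of which 186 were positive. For the abundant piRNAs the differences were 0.06 ± 0.03 for 21ur-3730 (adjusted p = 0.421), 0.06 ± 0.03 for 21ur-4572 (adjusted p = 0.369), 0.05 for 21ur-2446 (adjusted p = 0.592) and 0.01 for 21ur-739, with shared reads (adjusted p = 0.919). For 21ur-1 it was 0.04 (adjusted p = 0.579). Spermatogenic piRNAs had a median difference of 0.04 and Oogenic piRNAs of 0.03 (camera adjusted p = 5.4e-05 and 0.102, and adjusted p = 0.979 for both with an estimated correlation), and rescaling turned the Oogenic median to -0.00435.

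Decay in wild-type disl-2 was last set against the steady-state changes across piRNAs, which are not independent replicates. The Spearman correlation of slope with change was -0.15 for disl-2(how27), -0.15 for henn-1; disl-2, -0.29 for parn-1; disl-2, and -0.36 and -0.38 for the pup-1 double mutants with disl-2(how27) and disl-2(tm5337). A negative value means that piRNAs with faster loss had higher changes. It was 0.32 for disl-2(tm5337), 0.22 for the alleles together and 0.15 for pup-1. The sign was the same in each of the 4 abundance quartiles for all of these. Leaving out 1 library moved the disl-2(how27) value to between -0.21 and -0.06. The slopes of the genotypes correlated at 0.70. Germline class was not held fixed. Spermatogenic piRNAs had a steeper median slope than Oogenic ones (-0.13 and -0.09). Their median change was higher in disl-2(how27) (0.58 and 0.32) and parn-1; disl-2 (0.62 and -0.11), and lower in disl-2(tm5337) (-0.32 and -0.13). In pup-1 it was higher (-0.54 and -0.97), although the correlation was positive. For the alleles together it was 0.12 in both classes. Whether decay goes with change apart from class was not tested.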

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

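The tests of differences between effects, the tests on the disl-2(tm5337) profile, on the scaling and on disl-2(how27) replicate 1, and the test of disl-2(tm5337) on the cluster pattern, were chosen only after the result was seen.

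The alleles differed in a test of the difference itself. In the wild-type background 269 piRNAs were higher and 2836 lower in disl-2(tm5337) than in disl-2(how27), while in the pup-1 background 2 were higher. The effect of disl-2(how27) was higher for 297 and lower for 1034 piRNAs in pup-1 than in wild type, and that of disl-2(tm5337) higher for 1752 and lower for 768. The pup-1 double mutants carried pup-1 alleles that differ from each other and from that of the single mutant. The pup-1 values therefore cannot be laid to the disl-2 alleles alone. Against disl-2(how27) in wild type, the disl-2 effect in parn-1 was higher for 58 and lower for 310 piRNAs, and that in henn-1 higher for 343 and lower for 1350. The parn-1 double mutant carried disl-2(tm5337) and the henn-1 double mutant disl-2(how18), so allele and background cannot be told apart in these values. At 0 h of the TOFU-5 strain the effect of disl-2(how27) was lower for only 1 piRNA, but the median difference was -0.64 and 1677 of 5272 piRNAs had an unadjusted p under 0.05. The totals also went apart there, at log2 0.39 in wild type (0.31 to 0.47 with 1 library left out) and -0.35 at 0 h (-0.53 to -0.16). All but the pair of alleles within 1 background compare libraries of separate experiments. These differences use the authors' scaling and were not repeated after rescaling. Rescaling to equal medians brings the median change of any comparison close to 0 by construction. It was -0.04 in disl-2(how27), -0.07 in disl-2(tm5337) and -0.05 at 0 h, which cannot test the scaling. Whether more piRNAs were higher or lower therefore cannot be told apart from an effect of the scaling.

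The first pattern is the fall of 1511 piRNAs in disl-2(tm5337). Loss of DISL-2, acting alike in both alleles, is argued against as the whole cause, since those piRNAs had a median log2 change of 0.40 in disl-2(how27), or -0.15 after rescaling (SD over piRNAs 0.33), against -1.03 and -0.92 in disl-2(tm5337). The authors' scaling is argued against too, because 1546 piRNAs fell after rescaling. The same piRNAs lay lower than the others in pup-1 against its own control, by -0.47 in median log2, so a strain difference shared with the pup-1(tm1021) strain may account for part of the pattern. Which of the strain and the allele acts on which piRNA stays open, as does a small fall in disl-2(how27), where the sign of the median rests on the scaling. With the same allele in pup-1, 700 of 1453 of these piRNAs rose, against 1201 of all 5023 tested. Only 16 fell, where independent lists would share 137 falls. In parn-1, 307 of 1089 rose, against 826 of all 3456 tested, and 111 fell, against 112 for independent lists. The parn-1 counts thus lie near those of any such list. An effect of the allele alike in every strain would give more falls than independent lists, which neither shows. However, pup-1 and parn-1, over which these are measured, may carry the strain difference themselves. In pup-1 against its own control, 1030 of the 1453 fell, where independent lists would share 775. Rises measured over pup-1 start from that lower level.

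The second pattern is the rise in disl-2(how27). The test for disl-2(how27) replicate 1 alone gave a log2 difference in total of 0.31 without that library, which argues against it as the whole cause of the difference in total, although the number of rises was 1 without it. Rescaling left 76 piRNAs that rose, but a rise shared by most piRNAs and a scaling that favours the mutant libraries cannot be told apart, because the table holds no other small RNA to scale by. At 0 h of the TOFU-5 strain the same allele gave a total of 0.786 of wild type, a median log2 change of -0.20, and 4 rises against 64 falls. After rescaling, which by itself brings the median change close to 0, there were 3 and 2. The number of falls also depended on which library was left out. Neither the rise nor a fall is therefore secure there.

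The third pattern is the larger gain of cluster a than cluster b in the disl-2(how27), henn-1; disl-2 and parn-1; disl-2 comparisons, whose libraries are separate. Among piRNAs in neither germline class the smallest of the 3 differences in median was 0.29, among piRNAs with whole reads 0.28, and among those with a mean of at least 5 RPM 0.34. These argue against the authors' germline classes, shared reads and low values as the whole cause. A piRNA without a class may still depend on germline stage, so stage itself is not excluded. In disl-2(tm5337) against the control the difference was -0.0247, which argues against loss of DISL-2 as a cause that acts alike in every strain. With the same allele it was 0.82 in parn-1 and 0.16 in pup-1 (0.10 among piRNAs in neither class), and with disl-2(how27) it was 0.30 in pup-1 (0.19 among those) and 0.31 at 0 h of the TOFU-5 strain (0.27 to 0.33 with 1 library left out), while pup-1 alone, over which both pup-1 values are measured, had -0.43, so the strain background stays open as an untested part. A dependence on DISL-2 that differs between the clusters may be held as a hypothesis only.

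For the slower decay in disl-2(how27), 6 of 100 splits of the libraries within time points, the real one included, gave a median slope difference as large as the real 0.0329, the highest other being 0.0427, so chance cannot be excluded for that median.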

How the results depend on the processing

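The limma voom runs, the fit without disl-2(tm5337) libraries and the lists by authors' class were chosen only after the result was seen. The cause of each change below was not tested, except that a mean of at least 5 RPM leaves fewer piRNAs to test and a left-out library leaves fewer samples. Fewer samples do not account for counts that went up, as in henn-1; disl-2 without either henn-1 library. A lone henn-1 library adds nothing to the spread, which then came from the henn-1; disl-2 pair alone. That pair had a chi-square per degree of freedom of 4.54, against 38.6 in henn-1. The planned count-based test was not run, since the values were not whole reads. Of 1845 repeats for named piRNAs, 1682 kept their direction and side of the threshold, 148 lost the call, 8 gained it and 7 turned direction. For the lists, 64 of 156 lost their side of the threshold with an estimated correlation.

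With no filter, disl-2(how27) gave 0 rises and 0 falls by limma, the alleles pooled 20 and 25, parn-1; disl-2 0 and 0, pup-1; disl-2(tm5337) 639 and 232, the 0 h comparison 20 falls, and decay 51 rises in wild type and 48 in disl-2(how27). With a mean of at least 5, the rises and falls were 652 and 1 in disl-2(how27), 733 and 552 in henn-1; disl-2, 246 and 150 in parn-1; disl-2, 120 and 1340 in pup-1, 829 and 370 in pup-1; disl-2(how27), 2 and 134 at 0 h, 4 and 1330 for decay in wild type, and 3 and 1123 for decay in disl-2(how27). There were 309 rises in disl-2(tm5337), 253 for the alleles pooled and 212 falls in pup-1; disl-2(tm5337).

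Rescaled to equal medians, the rises and falls were 76 and 98 in disl-2(how27), 974 and 1087 in pup-1, 469 and 550 for decay in wild type, and 99 and 61 for decay in disl-2(how27). There were 1248 rises in disl-2(tm5337), and falls numbered 922 for the alleles pooled, 1387 in henn-1; disl-2, 756 in parn-1; disl-2, 767 in pup-1; disl-2(tm5337) and 2 at 0 h. The change of 21ur-2446 in disl-2(how27) turned to -0.10, and slopes turned to 0.00406 for 21ur-1, 0.0707 for 21ur-73 and 0.0814 for 21ur-2545 in wild type, and to 0.0101 for 21ur-1 and 0.0414 for 21ur-5059 in disl-2(how27). Rescaling takes out the slope of the library medians, -0.122 per hour in wild type and -0.0863 in disl-2(how27). The slopes that turned were shallower than that.

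One fit over all libraries gave 481 rises and 1 fall in disl-2(how27), 433 and 131 for the alleles pooled, and 41 falls at 0 h. Voom gave 1 fall in disl-2(how27), 433 rises for the alleles pooled, 108 falls at 0 h and 4 rises for decay in disl-2(how27). Without the disl-2(tm5337) libraries disl-2(how27) gave 1908 rises and 4 falls. A pseudocount of 0.1 gave 2 rises at 0 h. Without the 12 h time point decay had 2 rises in wild type and 51 rises and 1433 falls in disl-2(how27), 21ur-5493 turned to -0.00999, and the wild-type half-life was 6.12 h. The slope difference in totals was 0.0258 without 0 h and 0.0357 for the median piRNA (exact permutation p = 0.241 and 0.0928).

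The median piRNA in place of the total gave log2 differences of 0.58 in disl-2(how27), -0.19 in disl-2(tm5337), 0.22 for the alleles pooled, 0.12 in pup-1; disl-2(how27) and 0.18 in pup-1; disl-2(tm5337), and turned henn-1; disl-2 from -0.26 to 0.25. The correlation of decay with change, with a mean of at least 5, was -0.24 in disl-2(how27), -0.19 in henn-1; disl-2, -0.36 in parn-1; disl-2, -0.39 in pup-1; disl-2(how27) and 0.77 between genotypes. With a pseudocount of 0.1 it was 0.28 in disl-2(tm5337), 0.16 for the alleles pooled, -0.21 in henn-1; disl-2, -0.31 in parn-1; disl-2 and -0.33 in pup-1; disl-2(how27).

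Replicates left out in turn gave ranges, with a lone library assumed to vary like the other groups. Rises ran from 1 to 462 in disl-2(how27), 427 to 983 in disl-2(tm5337), 214 to 1184 for the alleles pooled, 448 to 3423 in henn-1; disl-2, 398 to 1014 in parn-1; disl-2, 124 to 146 in pup-1, 673 to 1296 in pup-1; disl-2(how27), 432 to 1242 in pup-1; disl-2(tm5337), 0 to 2 at 0 h, and 0 to 12 for decay in disl-2(how27). Falls were 0 in each run of disl-2(how27), by limma, and ran from 93 to 394 for the alleles pooled, 118 to 2345 in henn-1; disl-2, 51 to 550 in parn-1; disl-2, 1778 to 2559 in pup-1, 369 to 1009 in pup-1; disl-2(how27), 136 to 341 in pup-1; disl-2(tm5337) and 0 to 17 at 0 h. The log2 total of the alleles pooled ran from -0.12 to 0.19, the disl-2(how27) half-life from 11.3 to 16.1 h and the slope difference from 0.0348 to 0.0393.

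The replicate numbers share only a number: their deviations correlated between -0.20 and 0.30 in the disl-2 experiment and between -0.58 and 0.61 in the time course. With the replicate block 1563 piRNAs rose and 4 fell in disl-2(how27), other counts stayed within 1.5 times, and the slope difference had an exact permutation p of 0.0185. Depth limits low piRNAs, since 3 reads came to as much as 0.341 RPM.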

Other observations

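All values in this part were chosen only after the data were seen, and no explanation was tested for them.

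A set of 23 piRNAs rose in disl-2(how27), henn-1; disl-2, parn-1; disl-2 and pup-1; disl-2(how27) alike, of 3309 tested in all 4 comparisons, where independent lists would share 5.40. These comparisons share no libraries. Taken in pairs, henn-1; disl-2 and pup-1; disl-2(how27) shared fewer rises than independent lists would, 130 against 221, with a Spearman correlation of -0.14. The other pairs shared more than independent lists. The set rests on the disl-2(how27) calls: it held 0 piRNAs without disl-2(how27) replicate 1, which left 1 rise there, 6 without replicate 2, 9 and 3 without control replicates 1 and 2, 2 with disl-2(how27) rescaled to equal medians, and 0 with all 4 comparisons rescaled. Among them were 21ur-9174, with log2 changes of 0.99, 1.44, 1.49 and 2.63, 21ur-7067, with 1.59, 0.93, 2.18 and 1.31, and 21ur-1414, with 1.52, 1.02, 1.25 and 2.04. Between disl-2(how27) and parn-1; disl-2 alone, 340 rises were shared against 165 for independent lists, with a Spearman correlation of 0.49 across piRNAs. After rescaling 24 were shared against 5.67, and without disl-2(how27) replicate 1 there were 0. Without control replicate 2 it was 40 against 22.9. The correlation ran from 0.35 to 0.52 with 1 library left out. The parn-1 double mutant carried disl-2(tm5337), but that allele in wild type did not share its rises beyond independent lists. It shared 88 rises with parn-1; disl-2 against 109 for independent lists, with a Spearman correlation of -0.06. Of 1089 piRNAs that fell in disl-2(tm5337), 307 rose in parn-1; disl-2, against 826 of all 3456 tested, which lies near the count of independent lists.

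The piRNA 21ur-1627, singled out after its values were seen, was present in some strains and at 0 in others. It was at 7.42 and 7.12 RPM in disl-2(tm5337), 10.6 and 7.89 RPM in pup-1, 39.7 and 75.1 RPM in henn-1, 15.1 and 16.6 RPM in henn-1; disl-2, and 0.948 and 0.992 RPM in parn-1. It was at 0 in both libraries of each control, of parn-1; disl-2 and of both pup-1; disl-2 double mutants, and at 0 and 0.0568 RPM in disl-2(how27). Against a floor of 3 reads per library it was at least 43.4-fold higher in disl-2(tm5337) than in the control, at least 62.7-fold higher in pup-1 than in its control, and at least 7.98-fold higher in parn-1 than in parn-1; disl-2.

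21ur-425, named across comparisons after its values were seen, fell in 5 of 8 comparisons by limma, with log2 changes of -0.91 in disl-2(how27), -2.01 in disl-2(tm5337), -0.96 in parn-1; disl-2, -1.94 in pup-1 and -1.31 at 0 h of the TOFU-5 strain. It lay at -0.68 in henn-1; disl-2 (adjusted p = 0.121), and at -0.18 and 0.57 in the pup-1 double mutants with disl-2(how27) and disl-2(tm5337) against pup-1 (adjusted p = 0.643 and 0.123). The disl-2(how27) and disl-2(tm5337) comparisons share their control libraries. With any 1 of the compared libraries left out, the calls in disl-2(tm5337) and pup-1 were kept, while the adjusted p ran from 0.0656 to 0.378 in disl-2(how27), from 0.0682 to 0.178 at 0 h, and from 0.00444 to 0.189 in parn-1; disl-2.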
